A study of Mus musculus with 4 samples.

How the data were processed

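RNA was measured by sequencing in 4 libraries of mouse ES-E14TG2a embryoid bodies, 1 for each of 4 groups: control, and ATRA-treated at 0, 6 and 10 days. Per the labels' protocols, total RNA was extracted, cDNA was made with oligo(dT) primers, and sequencing libraries followed Illumina methods. Whether the libraries were made from that cDNA is not given in the sources used here.

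The deposited values are FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library), per the file headers, with 1 column per library. Trimmomatic, TopHat and Cufflinks and the mm10 build are named per the submitters' processing notes, with no versions. The annotation, the use of strand in counting, and any filter are not given in the sources used here. FPKM divides by transcript length and by the library total, so a few very abundant transcripts lower every other value in their library, and reads shared by similar genes are split by a model.

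The table used here had 10201 rows with 9997 distinct symbols; 177 symbols had more than 1 row, whose values were summed. Gene positions came from GENCODE M21 on mm10, by current or older symbol, for 9820 symbols. The table held 7927 of the 9198 protein-coding genes (86.2%) of chromosomes 1 and 10 to 18, between 76.7% and 90.9% per chromosome, and 1 of 12702 on all other chromosomes. Genes elsewhere were not analysed here. This includes 5 of the 6 landmark genes chosen beforehand, leaving Pou5f1. Some genes of the lists are not reported here by name. A value of exactly 0 is written as "listed at 0", with no fold; 1211 symbols were listed at 0 in all 4 libraries.

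The table gives no counts. Depth was estimated from genes with 1 annotated transcript of 800 nt or more (1376 genes): their lowest values above 0, times length, pile up at the worth of 1 fragment. The median of such values between 0.02 and 0.05 FPKM times kb was 0.0408 in the control, 0.0379 at 0 days, 0.0397 at 6 days and 0.0366 at 10 days, hence about 24500000, 26400000, 25200000 and 27300000 fragments. These are estimates, and cover counting error only. Small RNAs shorter than a fragment get unstable FPKM; 512 symbols of small or ribosomal RNAs were counted in the totals but not named, apart from Rn45s, which is set beside 2 extreme genes.

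Differences were taken on log2(FPKM + 1) among the 5885 symbols at 1 FPKM or more in at least 1 library. A gene was called higher or lower at a difference of 2-fold or more. With 1 library per group there was no test, p-value or SD. The comparisons were the 3 successive steps and the 2 cumulative comparisons with the control.

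There were 32 gene lists fixed before the data were examined, with 241 of 543 entries in the table and 186 tested. Some genes stand in more than 1 list. For the 25 lists with 3 or more tested genes, the median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression (seed 1). This percentile describes these libraries and is no test. Of the 125 percentiles computed, 70 lay at or outside 2.5 and 97.5, where 6.25 would lie by chance if lists were random; genes of a list are co-regulated, so they are not independent. A further 5 lists were chosen after the values were seen and are given only in the closing section.

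Genes were named by a rule fixed beforehand: the 10 largest rises and 10 largest falls of each successive step, and the 5 largest of each against the control at 6 and 10 days, among genes at 5 FPKM or more in the higher library, passing over predicted genes and small RNAs; 2 to 4 members of each list with large differences; and the landmarks. Genes of other kinds named in the closing section were chosen after their values were seen.

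The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 FPKM, median-ratio and upper-quartile scaling, and a 4-fold threshold. The median-ratio factors were 1.096 for the control and 0.975, 0.969 and 0.965 for 0, 6 and 10 days. Keeping the highest row of a repeated symbol, and leaving out small and ribosomal RNAs, were added after seeing the data.

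The steps were tested on simulated libraries with Poisson counting error at the estimated depths, 5666 genes each. Of these, 200 were changed 3-fold or 6-fold, all picked among genes at 5 FPKM or more before the change. For the simulated comparison of 0 days with the control, 100% of the changed genes were called at each fold size, and 3 of 5466 unchanged genes were called; the other comparisons gave 100% and between 1 and 6. These numbers leave out biological variation. The 100% does not cover genes below 5 FPKM, where adding 1 to the FPKM shrinks differences and no change was planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.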

Results

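RNA was profiled by sequencing in embryoid bodies, the aggregates that embryonic stem cells form in suspension, grown from the mouse embryonic stem cell line ES-E14TG2a. The series asks how the transcriptome changes while all-trans retinoic acid (ATRA), the signalling form of vitamin A used to direct such cells towards neurons, drives differentiation. There were 4 libraries, each the only one of its group: control embryoid bodies, and ATRA-treated embryoid bodies labelled 0, 6 and 10 days. ATRA was given at 5 µM on days 4 and 6 of embryoid body culture, and embryoid bodies were moved to coated dishes after 8 days in suspension. The labels do not give the culture day of the control, nor whether each library came before or after the transfer. Stage and culture format therefore cannot be separated. In every comparison with the control, ATRA treatment cannot be told apart from a difference in culture age. With 1 library per group no difference has a replicate check, and every value below describes these libraries.

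Levels are FPKM, and differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The table used here covers genes of chromosomes 1 and 10 to 18, and 5885 genes reached 1 FPKM in at least 1 library. The depth, estimated from the FPKM worth of 1 fragment, was 24500000 fragments in the control, 26400000 at 0 days, 25200000 at 6 days and 27300000 at 10 days. At 5 FPKM on a 1 kb transcript this gives 123 to 136 fragments, a counting error of 8.56% to 9.03%, and a level resting on 3 fragments is 0.110 to 0.122 FPKM. These errors cover counting only. The largest rises and falls named below are among genes at 5 FPKM or more in the higher library, with predicted genes and small RNAs passed over.

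The control library stood farthest from the 10-day library. Across 5885 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.848 between control and 0 days, 0.834 between control and 6 days, and 0.768 between control and 10 days. Among the ATRA libraries r was 0.900 between 0 and 6 days, 0.931 between 6 and 10 days, and 0.840 between 0 and 10 days. Of the 3047 genes that differed 2-fold or more between their highest and lowest library, 1199 were highest in the control, 546 at 0 days, 248 at 6 days and 1054 at 10 days. Which class was largest depended on the scaling: median-ratio scaling gave 912 genes highest in the control and 1166 at 10 days, and upper-quartile scaling 921 and 959.

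**Figure D1:**
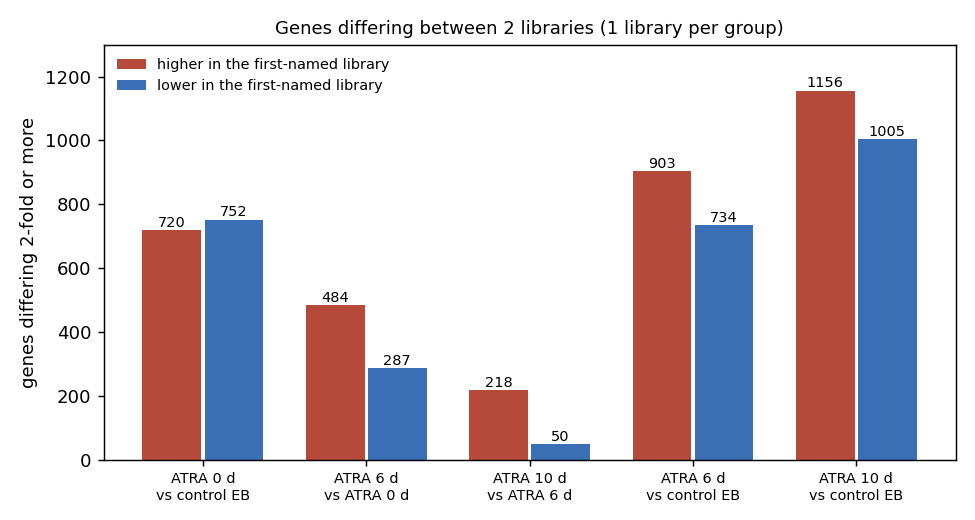
Number of genes (vertical axis) that were 2-fold or more higher or lower in the first-named of 2 libraries, for the 3 successive steps and the 2 comparisons with the control; each bar is a count from 1 library against 1 library, so there are no error bars. The first step has 720 genes higher and 752 lower, and the last step 218 higher and 50 lower.

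The first comparison asked what ATRA-treated embryoid bodies at 0 days expressed that control embryoid bodies did not. All 4 tested Hox genes of paralog groups 1 to 4 and all 7 of groups 5 to 9, which pattern the hindbrain and spinal cord, were higher at 0 days. So were 5 of 7 genes of retinoic acid signalling, and 10 of 11 pluripotency genes were lower. Pou5f1, the core pluripotency factor Oct4, stood at 1241 FPKM in the control and 97.4 FPKM at 0 days. All 5 germ line genes were higher, led by Rec8, a meiotic cohesin subunit, at 3.57 FPKM in the control and 87.1 FPKM at 0 days. In all, 720 genes were 2-fold or more higher and 752 lower, of which 192 and 153 differed 4-fold or more.

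All 4 tested Hox genes of paralog groups 1 to 4 were higher at 0 days, with a median log2 difference of 5.41 (percentile 99.99 among 10000 random lists of the same size matched on mean expression). Hoxb1 (mm10 chromosome 11, 96365752 to 96368256, plus strand) went from 0.0189 to 31.5 FPKM, Hoxb2 from 0.0503 to 52.4 FPKM, Hoxb3 from 0.105 to 40.6 FPKM and Hoxc4 from 0.317 to 62.4 FPKM. All 7 tested genes of groups 5 to 9 were higher too (median 3.06, above all 10000 random lists). Their largest difference was in Hoxb5 (chromosome 11, 96303336 to 96306121), at 0.0294 FPKM in the control and 56.2 FPKM at 0 days, followed by Hoxb8 (0.0176 to 37.8 FPKM) and Hoxc5 (0.0426 to 26.5 FPKM). Hoxb5os, antisense to Hoxb5, went from 0.0812 to 47.1 FPKM, but whether strand was used in counting is not given in the sources used here, so its reads cannot be told from those of Hoxb5. Of groups 10 to 13, 2 genes were tested. Hoxb13 was higher (0.200 to 3.46 FPKM), and Hoxc13 was at 0.362 and 0.506 FPKM.

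Of 7 tested genes of retinoic acid metabolism and response, 5 were higher and none lower by 2-fold (median 2.65, above all 10000 random lists). Meis1, which encodes a cofactor of Hox proteins, went from 0.294 to 29.4 FPKM. Rarb, which encodes a retinoic acid receptor and is itself a direct target of the receptors (chromosome 14, 16430839 to 16819156), went from 0.630 to 16.9 FPKM. Nrip1, a receptor corepressor, went from 1.55 to 15.1 FPKM and Cdx1, a caudal-type homeobox gene, from 0.441 to 4.91 FPKM. Rara was at 10.6 and 20.8 FPKM and Rarg at 79.5 and 42.4 FPKM, both short of 2-fold on this scale.

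All 5 tested germ line genes were higher at 0 days (median 1.76, percentile 99.8). Beside Rec8 (chromosome 14, 55618037 to 55625395), Dazl, an RNA-binding protein of germ cells, went from 2.80 to 22.2 FPKM, and Ddx4 (Vasa) from 4.63 to 18.1 FPKM. Other high risers were Gas1, a cell-surface protein that binds hedgehog ligands (0.843 to 88.7 FPKM), Dlk1 (0.238 to 41.9 FPKM), and the insulin-like growth factor binding proteins Igfbp4 (0.404 to 47.0 FPKM) and Igfbp5 (0.117 to 35.3 FPKM).

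Of 11 tested pluripotency genes, 10 were lower at 0 days and none higher (median -2.97, below all 10000 random lists). Tdh, threonine dehydrogenase, which mouse embryonic stem cells depend on (chromosome 14, 63492347 to 63509092), had the largest fall of this step among the genes named by rule, from 195 to 0.873 FPKM. Esrrb, a nuclear receptor of the naive state (chromosome 12, 86361117 to 86521628), went from 129 to 3.75 FPKM, Dnmt3l from 202 to 15.0 FPKM and Klf5 from 248 to 30.8 FPKM. Lin28b was the exception, at 6.62 and 5.74 FPKM. Further large falls were in Tcl1, a coactivator of Akt (101 to 0.905 FPKM), Etv4 (93.1 to 0.949 FPKM), Spry4 (67.4 to 1.42 FPKM) and Sept1 (217 to 3.39 FPKM). The rest of the 10 largest were the keratins Krt17 (45.3 to 0.463 FPKM) and Krt42 (37.4 to 0.405 FPKM), Gpx2 (96.3 to 3.03 FPKM) and Ly6a (34.7 to 0.501 FPKM).

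Of 9 tested cell cycle genes, 6 were lower (median -1.24, percentile 0.14), among them Rrm2, a subunit of ribonucleotide reductase (299 to 49.3 FPKM), and the mitotic cyclin Ccnb1 (279 to 88.2 FPKM). Of 10 genes of DNA methylation and Polycomb, 5 were lower and 1 higher (median -0.94, percentile 0.23). Tet1 went from 29.5 to 3.76 FPKM and Uhrf1 from 177 to 42.1 FPKM, while the methyltransferase Dnmt3a was higher, at 5.97 and 20.4 FPKM. The 5 reference genes also had lower values at 0 days, with a median of -0.74 (percentile 21.7). Of these, Ppia was 2-fold lower (5055 to 2183 FPKM), and Tbp was at 30.2 and 17.8 FPKM.

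Lineage lists gave a mixed first step. Of 7 neural progenitor genes 4 were higher (median 1.76, above all 10000 random lists), including Dach1 (0.0159 to 15.1 FPKM), Nr2f1 (0.0874 to 12.3 FPKM) and Cdh2, N-cadherin (0.219 to 4.27 FPKM). Of 11 neural crest genes 6 were higher and 1 lower (median 1.24, percentile 99.97). Ednrb, the endothelin receptor of crest cells, was at 0.129 and 30.4 FPKM and Sox9 at 0.0380 and 5.32 FPKM, while Ngfr was lower, at 14.1 and 1.98 FPKM. Of 14 genes of extraembryonic and definitive endoderm 8 were higher and 1 lower (median 1.12, above all 10000 random lists). They are called endoderm genes below, and the list does not separate the extraembryonic from the definitive kind. Ttr (transthyretin) was at 1.07 and 15.4 FPKM and Apoa2 at 0.107 and 6.24 FPKM. Of 10 tested genes of the epithelial and trophoblast list 4 were higher and 1 lower (median 0.61, percentile 99.6). The trophoblast transcription factors of this list lie on chromosomes outside the table, so its values describe epithelial genes, here and below. In the proneural list 2 of 10 genes were higher and 1 lower (median 0.37, percentile 89.3). Sox11 (1.19 to 12.4 FPKM) and Gadd45g (3.53 to 24.7 FPKM) were the higher ones. The pan-neuronal list did not stand apart (1 of 8 higher, 1 lower; median -0.03, percentile 26.7), and its median was above 0 under both other scalings. Glycolysis and hypoxia genes had a median of 0.51 (2 of 4 higher, percentile 98.1) and immediate early and stress genes a median of 0.82 (2 of 6 higher, percentile 99.0).

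Medians within the range of random lists at this step were found for primed epiblast genes (3 of 6 higher, 2 lower; 0.38), primitive streak genes (1 of 4 higher; 0.00), synaptic genes (1 of 3 lower; 0.58), and hindbrain and spinal subtype genes (1 of 3 higher; 0.67). The same held for glial genes (2 of 6 higher; 0.42), hedgehog and Wnt targets (1 of 9 higher, 1 lower; 0.39), cardiac and muscle genes (1 of 8 lower; 0.06), endothelial and blood genes (1 of 3 lower; 0.00) and mesenchyme genes (3 of 9 higher; 0.17). The primitive streak median of 0.00 took the opposite sign under both other scalings. The list of hedgehog and Wnt targets, here and below, also holds ligands of these pathways.

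The balance of higher and lower genes in this step depended on the scaling. Median-ratio scaling moved the median gene by 0.11 and upper-quartile scaling by 0.18 relative to the deposited FPKM. The share of higher genes among those that differed went from 48.9% to 60.6% and 65.5%. Under these scalings the pluripotency median was -2.81 and -2.72, the reference gene median -0.57 and -0.49, and the cell cycle median -1.08 and -0.99. Upper-quartile scaling gave 497 lower genes, and a pseudocount of 0.1 gave 1111 higher genes.

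The second comparison, between 6 and 0 days of the ATRA series, asked what was added as the embryoid bodies developed further. All 10 epithelial genes, 12 of 14 endoderm genes and 5 of 9 extracellular matrix genes were higher at 6 days. All 4 Hox genes of groups 1 to 4 and 5 of 7 retinoic acid genes were lower, and 4 of 8 pan-neuronal genes were higher. Spink1, a secreted trypsin inhibitor, had the largest rise among the genes named by rule (chromosome 18, 43728082 to 43737557), from 17.6 to 1122 FPKM. Genes that were 2-fold or more higher numbered 484, and 287 were lower; 133 and 47 differed 4-fold or more.

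All 10 epithelial genes were higher at 6 days (median 2.43, above all 10000 random lists). Krt7, a keratin of simple epithelia, led (chromosome 15, 101411043 to 101430313), going from 3.83 to 140 FPKM. The claudins Cldn7 and Cldn6 went from 9.68 to 76.7 FPKM and from 57.2 to 325 FPKM, Krt18 from 120 to 743 FPKM, Krt8 from 102 to 753 FPKM and Krt19 from 57.4 to 294 FPKM. Of 14 genes of extraembryonic and definitive endoderm 12 were higher and 1 lower (median 2.58, above all 10000 random lists). Sox17, an endoderm transcription factor, went from 1.87 to 39.6 FPKM, Dab2 from 16.9 to 184 FPKM, Ttr (chromosome 18, 20665280 to 20674321) from 15.4 to 183 FPKM. Sparc, a secreted matrix protein abundant in parietal endoderm, went from 259 to 1862 FPKM. Sox7 was lower, at 19.6 and 5.48 FPKM. Of 9 mesenchyme and matrix genes 5 were higher (median 1.06, percentile 99.9), with Col3a1 at 0.123 and 20.4 FPKM and Col1a1 at 1.79 and 14.6 FPKM. Cardiac and muscle genes had a median of 0.83 (3 of 8 higher, 1 lower; percentile 99.9). Tnnc1, cardiac troponin C, went from 2.05 to 45.7 FPKM and Hand1 from 0.123 to 9.44 FPKM.

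Of 8 pan-neuronal genes 4 were higher at 6 days (median 0.71, percentile 99.1). Nefl, neurofilament light chain (chromosome 14, 68083863 to 68089095), went from 2.58 to 39.6 FPKM, Tagln3 from 1.78 to 15.7 FPKM, Dpysl3 from 3.18 to 9.10 FPKM and Map2 from 1.82 to 4.74 FPKM. Proneural genes had a median of 0.72 (2 of 10 higher, percentile 99.6), the higher ones being Nhlh1 (0.108 to 2.79 FPKM) and Hes6 (12.4 to 33.4 FPKM). Fabp7, a fatty acid binding protein of radial glia (chromosome 10, 57784881 to 57788450), went from 1.13 to 35.9 FPKM. The neural progenitor list as a whole had 3 of 7 genes higher and 2 lower (median 0.51, percentile 94.6). Dach1 was among the lower ones, at 15.1 and 4.59 FPKM. Neural crest genes had a median of 0.51 (3 of 11 higher, 1 lower; percentile 98.3). The list of hedgehog and Wnt targets and ligands had a median of 0.60 (3 of 9 higher, percentile 98.4), with the ligand Wnt1 at 0.636 and 6.72 FPKM.

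Hox genes of groups 1 to 4 were all lower at 6 than at 0 days (median -2.31, percentile 0.02), and Hoxb1 fell furthest, from 31.5 to 0.480 FPKM. In groups 5 to 9, 3 of 7 were lower and 1, Hoxc6 (4.60 to 14.9 FPKM), was higher (median -0.47, percentile 6.62). Of the retinoic acid list 5 of 7 were lower (median -1.85, below all 10000 random lists), including Nrip1 (15.1 to 2.70 FPKM) and Rarb (16.9 to 3.97 FPKM). All 5 germ line genes were lower (median -1.70, percentile 0.015), with Dazl at 22.2 and 1.18 FPKM and Rec8 at 87.1 and 11.5 FPKM. The immediate early genes Egr1 (129 to 6.84 FPKM) and Fos (72.2 to 5.35 FPKM) were lower, while their list as a whole was not (2 of 6 lower; median -0.06, percentile 40.1). Prph, peripherin (32.7 to 3.56 FPKM), Raet1a (71.3 to 6.14 FPKM), Mrc2 (31.5 to 4.57 FPKM), Ndufa4l2 (86.0 to 14.1 FPKM) and Gas1 (88.7 to 12.1 FPKM) complete the 10 largest falls.

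Other large rises were in Vtn, vitronectin (0.0777 to 30.9 FPKM), Car4 (5.60 to 141 FPKM), and Igfbp1 (a log2 difference of 4.17 from 0.224 FPKM). The trophoblast genes Prl2b1 and Tpbpa were both listed at 0 at 0 days, and stood at 19.3 and 19.2 FPKM at 6 days. Tdh was among the 10 largest rises as well, from 0.873 to 34.3 FPKM, while the pluripotency list had 2 of 11 genes higher and a median of 0.14 (percentile 74.6). Primitive streak genes had a median of 1.15 (3 of 4 higher, percentile 99.6), with T, brachyury, at 0.0176 and 5.44 FPKM. Genes of DNA methylation and Polycomb had a median of -0.52 (1 of 10 lower, percentile 0.23), and those of glycolysis and hypoxia a median of 0.83 (2 of 4 higher, percentile 98.1).

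Lists within the random range at this step were primed epiblast (1 of 6 higher, 2 lower; median -0.31), synaptic (none of 3 differing; 0.27), hindbrain and spinal subtypes (1 of 3 higher; -0.69), glia (1 of 6 lower; -0.45), and endothelial and blood (1 of 3 higher; 0.49). So were cell cycle (none of 9 differing; 0.00, with a change of sign under median-ratio scaling) and reference genes (none of 5 differing; 0.33). A pseudocount of 0.1 gave 473 lower genes for this step.

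**Figure D2:**
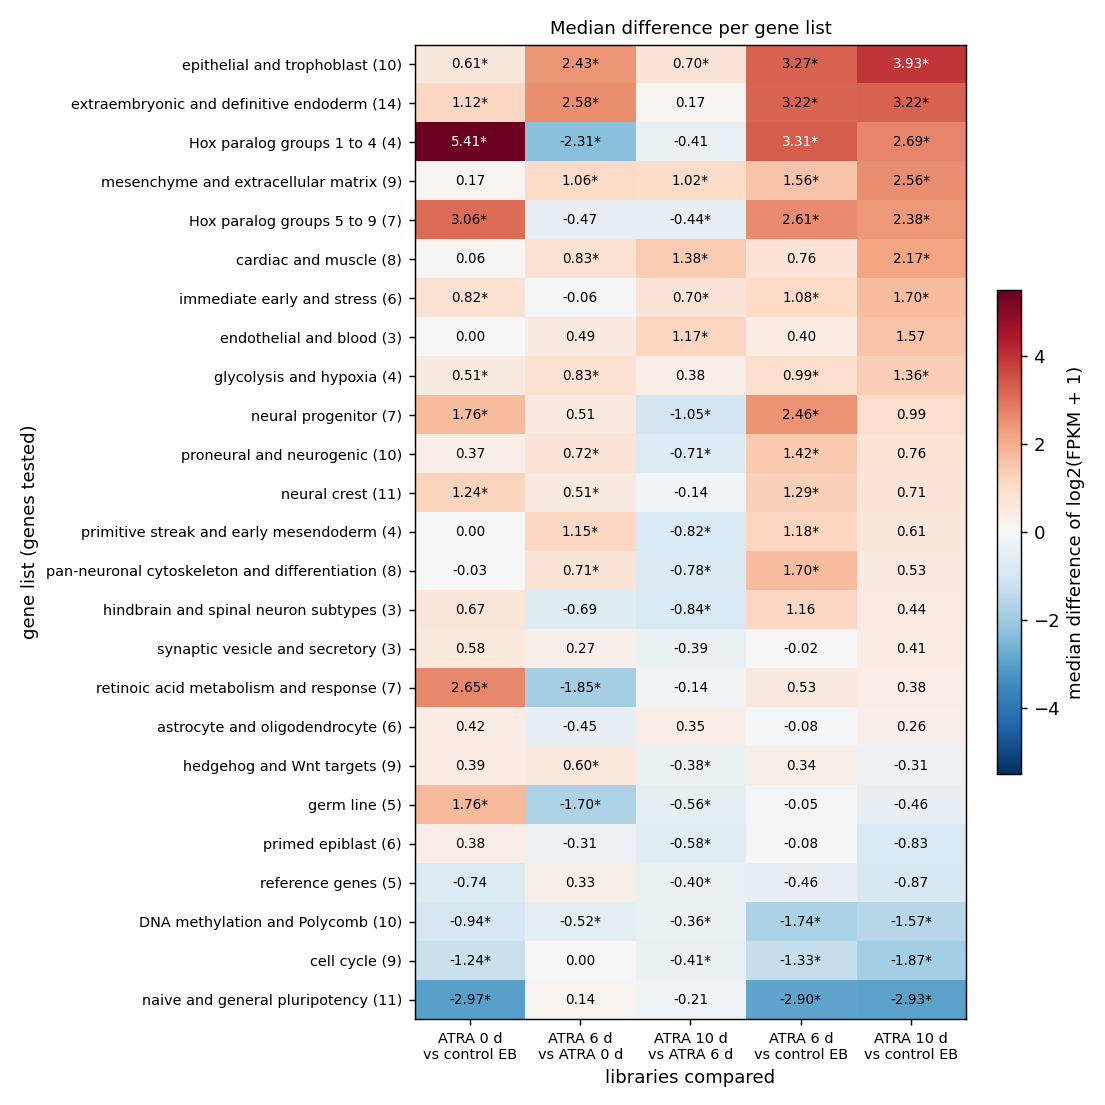
Median difference of log2(FPKM + 1) for the 25 gene lists with 3 or more tested genes (rows, number of tested genes in parentheses) in the 5 comparisons (columns); red is higher and blue lower in the first-named library, and a star marks medians at or outside percentiles 2.5 and 97.5 of 10000 matched random lists. The pluripotency median is -2.97 in the first step and lies between -0.21 and 0.14 in the later steps, while the epithelial median is 2.43 in the second step.

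The third comparison, 10 against 6 days, asked how the ATRA-treated embryoid bodies changed late in the series. It was the smallest step, with 218 genes 2-fold or more higher and 50 lower, and 29 and 7 at 4-fold. Of the muscle genes 6 of 8 and of the matrix genes 5 of 9 were higher at 10 days, and placental prolactins were among the largest rises. Of 25 genes in the neural progenitor, proneural and pan-neuronal lists 8 were lower and 1 higher than at 6 days, and the median of each list lay below all 10000 random lists.

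Of 8 cardiac and muscle genes 6 were higher at 10 days (median 1.38, above all 10000 random lists). Tnnc1 (chromosome 14, 31208312 to 31211729) went from 45.7 to 217 FPKM, Myl7, the atrial myosin light chain, from 8.57 to 65.7 FPKM, and Myl4 from 4.12 to 13.3 FPKM. Of 9 mesenchyme genes 5 were higher (median 1.02, above all 10000 random lists), including Col1a1 (14.6 to 42.8 FPKM), Dcn, decorin (4.83 to 13.9 FPKM) and Lox, a collagen cross-linking enzyme (0.841 to 5.15 FPKM). Epithelial genes had a median of 0.70 (2 of 10 higher, percentile 99.99), with Krt18 (chromosome 15, 102028180 to 102032027) at 743 and 1518 FPKM and Cldn7 at 76.7 and 182 FPKM. Endoderm genes had a median of 0.17 (1 of 14 higher, percentile 85.3), the higher one being Apoa2 (40.8 to 146 FPKM). The largest rises were in Ccl20, a chemokine (4.56 to 62.1 FPKM), Psca (12.7 to 151 FPKM), Ccl7 (2.70 to 17.2 FPKM) and Hba-x, embryonic alpha globin (0.402 to 6.99 FPKM). They also included Ctsj, a placental cathepsin (8.91 to 43.1 FPKM), and the placental prolactins Prl8a9 (2.01 to 22.3 FPKM), Prl2c3 (0.447 to 8.94 FPKM) and Prl3b1 (0.669 to 6.37 FPKM). The Prl2c genes are near-identical copies of each other, so the value of Prl2c3 is uncertain. Endothelial and blood genes had a median of 1.17 (2 of 3 higher, percentile 99.7). Immediate early and stress genes had one of 0.70 (2 of 6 higher, percentile 99.9), with Ddit3, a stress-induced transcription factor, at 47.3 and 117 FPKM.

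Of 7 neural progenitor genes 4 were lower at 10 than at 6 days (median -1.05, below all 10000 random lists). Fabp7 was at 35.9 and 16.8 FPKM, Dach1 at 4.59 and 0.958 FPKM, Cdh2 at 6.48 and 2.42 FPKM, and Pax3 at 1.97 and 0.433 FPKM. Pan-neuronal genes had a median of -0.78 (2 of 8 lower, below all 10000 random lists), with Tagln3 at 15.7 and 5.87 FPKM and Map2 at 4.74 and 1.02 FPKM. Proneural genes had a median of -0.71 (2 of 10 lower, 1 higher, below all 10000 random lists). Sox11 was at 11.8 and 4.95 FPKM and Nhlh1 at 2.79 and 0.557 FPKM, while Gadd45g was higher, at 31.6 and 67.8 FPKM. The 10 largest falls included Tagln3, given above. They also included the neuronal genes Sept3 (6.69 to 1.64 FPKM), Sst, somatostatin (8.02 to 2.68 FPKM), and Nsg2 (18.0 to 7.19 FPKM). Apart from Ispd and Filip1l, described next, the rest were Pantr1, Ednrb, brachyury (symbol T) and Dhx9. The noncoding RNA Pantr1 went from 13.5 to 5.14 FPKM and Ednrb from 17.1 to 6.57 FPKM. Brachyury went from 5.44 to 0.776 FPKM, and Dhx9, an RNA helicase, from 50.7 to 21.2 FPKM.

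The 2 largest falls had extreme values and are uncertain. Ispd (chromosome 12, 36381450 to 36689503) was at 11919 FPKM at 6 days and 1.01 FPKM at 10 days, and Filip1l (chromosome 16, 57353093 to 57573126), which overlaps Cmss1 on the other strand, was at 12131 and 1379 FPKM. The ribosomal RNA precursor Rn45s was at 2629 and 402 FPKM in the same libraries.

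Medians below the random range at 10 days were also found in primed epiblast genes (2 of 6 lower; median -0.58, percentile 0.06), primitive streak genes (1 of 4 lower; -0.82, percentile 0.02), Hox groups 5 to 9 (2 of 7 lower; -0.44, percentile 0.62). They were also found in hindbrain and spinal subtype genes (1 of 3 lower; -0.84, percentile 0.28), hedgehog and Wnt targets (3 of 9 lower; -0.38, percentile 0.77) and germ line genes (none of 5 differing 2-fold; -0.56, percentile 0.51). Cell cycle genes (none of 9; -0.41, percentile 0.115) and genes of DNA methylation and Polycomb (none of 10; -0.36, percentile 0.38) were below the range too. The reference genes lay in the same range, with a median of -0.40 (none of 5; percentile 1.16). Lists within the random range were pluripotency (none of 11; -0.21), retinoic acid (none of 7; -0.14), and Hox groups 1 to 4 (none of 4; -0.41). The same held for synaptic (none of 3; -0.39), glia (none of 6; 0.35), neural crest (2 of 11 lower; -0.14) and glycolysis (none of 4; 0.38).

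For this step a pseudocount of 0.1 gave 363 genes higher and 185 lower, and upper-quartile scaling, which moved the median gene by -0.11, gave 67.5% higher genes in place of 81.3%. Both the second and the third comparison use the 6-day library, so an extreme value there enters them with opposite signs.

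Against the control, 903 genes were 2-fold or more higher and 734 lower at 6 days, and 1156 were higher and 1005 lower at 10 days. Krt7 (0.0976 FPKM in the control, 140 at 6 days and 260 at 10 days), Ttr (1.07, 183 and 356 FPKM) and Krt18 (12.8, 743 and 1518 FPKM) were among the 5 largest rises at both times. The others were Igfbp4 (59.5 FPKM) and Spink1 (1122 FPKM) at 6 days, and Apoa2 (146 FPKM) and Tnnc1 (217 FPKM) at 10 days. Arc, an activity-regulated gene of neurons, was lower at both (62.5 FPKM in the control, 1.91 and 2.18 FPKM), as were Sept1 (217, 9.25 and 10.3 FPKM) and Esrrb (129, 6.78 and 4.85 FPKM). Cobl (25.6 to 0.576 FPKM) and Sntg1 (17.3 to 0.147 FPKM) were among the 5 largest falls at 6 days, and Ispd (5462 to 1.01 FPKM) and Dppa2 (54.8 to 2.32 FPKM) at 10 days. Of the 720 genes higher at 0 days, 447 were still 2-fold or more above the control at 6 days and 465 at 10 days, and 147 had dropped back 2-fold or more from 0 to 6 days. Of the 752 lower genes, 457 were still lower at 6 days and 503 at 10 days, and 100 had risen back 2-fold or more from 0 to 6 days. The 0-day library enters both comparisons behind the return counts with opposite signs, which favours returns. Independent lists of these sizes would share 110 and 141 higher genes and 93.8 and 128 lower genes. In 100 simulations of unchanged libraries with counting error alone, the shared control gave at most 3 such genes. Variation between cultures is not in that number, so part of the overlap may come from the shared control.

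**Figure D3:**
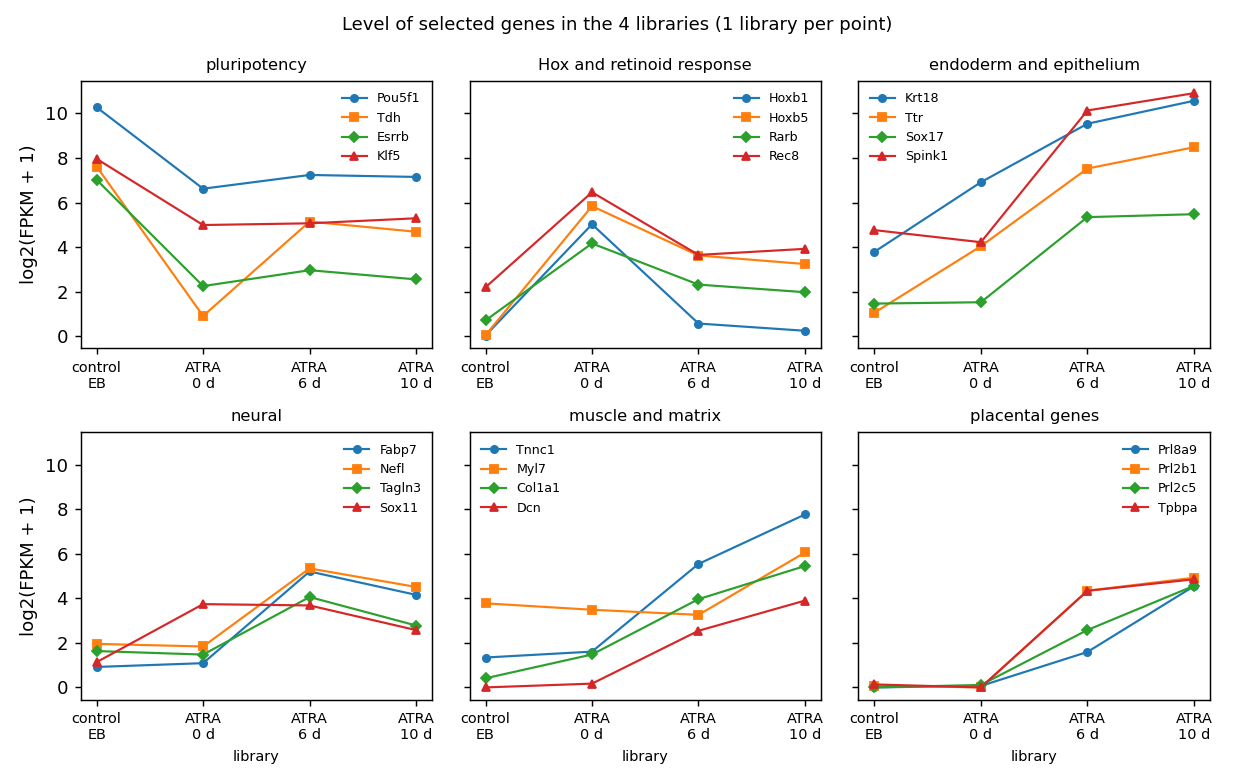
Level of 24 genes as log2(FPKM + 1) (vertical axis) in the control and the 3 ATRA libraries (horizontal axis), grouped by kind; each point is 1 library and the lines only join the points of a gene. The genes shown were picked after their values were seen; Pou5f1 goes from 1241 FPKM to 97.4 FPKM in the first step, Hoxb1 peaks at 31.5 FPKM at 0 days, and Tnnc1 reaches 217 FPKM at 10 days.

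Over the whole series the pluripotency genes stayed low (10 of 11 lower at both times; medians -2.90 at 6 days and -2.93 at 10 days, below all 10000 random lists), with Pou5f1 (chromosome 17, 35506018 to 35510772) at 150 and 141 FPKM. Epithelial genes had medians of 3.27 and 3.93 (9 of 10 higher at both times), and endoderm genes 3.22 and 3.22 (13 of 14 higher at both times). These 4 medians lay above all 10000 random lists. Mesenchyme genes had medians of 1.56 (6 of 9 higher, percentile 99.9) and 2.56 (8 of 9 higher, above all random lists). Cardiac and muscle genes reached 2.17 at 10 days (6 of 8 higher, 1 lower; percentile 99.98) after 0.76 at 6 days (percentile 97.0). Hox groups 1 to 4 (3.31 and 2.69; 3 of 4 higher at both times) and groups 5 to 9 (2.61 and 2.38; 7 of 7 higher at both times) remained above the control, at percentiles of 99.8 or more.

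The medians of the neural progenitor, proneural and pan-neuronal lists against the control were higher at 6 days than at 0 or 10 days. Neural progenitor genes had medians of 2.46 at 6 days (5 of 7 higher, above all random lists) and 0.99 at 10 days (3 of 7, percentile 91.7). Proneural genes had 1.42 (8 of 10 higher, 1 lower, above all random lists) and 0.76 (3 higher, 1 lower, percentile 95.7), and pan-neuronal genes 1.70 (5 of 8 higher, 2 lower, percentile 99.9) and 0.53 (4 higher, 1 lower, percentile 78.8). Neural crest genes had 1.29 (7 of 11 higher, 1 lower, percentile 99.8) and 0.71 (5 higher, 1 lower, percentile 87.9). Nefh, the neurofilament heavy chain, ran the other way, at 2.72 FPKM in the control and 0.206 FPKM at 10 days. Synaptic genes (-0.02 and 0.41; the first positive under both other scalings), hindbrain and spinal subtypes (1.16 and 0.44) and glial genes (-0.08 and 0.26) lay within the random range at both times. So did retinoic acid genes (0.53 and 0.38), primed epiblast genes (-0.08 and -0.83; the first positive under both other scalings), germ line genes (-0.05 and -0.46; likewise), hedgehog and Wnt targets (0.34 and -0.31) and endothelial and blood genes (0.40 and 1.57). Primitive streak genes were above it at 6 days (1.18, percentile 98.3) and not at 10 days (0.61, percentile 70.1).

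Cell cycle genes (-1.33, with 5 of 9 lower, and -1.87, with 6 of 9 lower) and genes of DNA methylation and Polycomb (-1.74, with 6 of 10 lower, and -1.57, with 8 of 10 lower) had medians below the control at both times, at percentiles of 0.01 or less. Jarid2, a subunit of Polycomb repressive complex 2, was at 53.3 FPKM in the control and 7.59 FPKM at 10 days, and Mcm3, a subunit of the replicative helicase, at 220 and 57.8 FPKM. The 5 reference genes had medians of -0.46 at 6 days (percentile 21.7) and -0.87 at 10 days (percentile 5.36), and all 5 were highest in the control. Stress genes had medians of 1.08 (3 of 6 higher, 2 lower; percentile 99.3) and 1.70 (4 higher, 2 lower; percentile 99.7). Glycolysis and hypoxia genes had 0.99 (2 of 4 higher, percentile 98.9) and 1.36 (3 higher, percentile 99.1). P4ha1 led the last list, at 24.3 FPKM in the control and 228 FPKM at 10 days. At 6 days upper-quartile scaling gave 67.5% higher genes in place of 55.2%, and at 10 days median-ratio scaling gave 63.2% in place of 53.5%. Median-ratio scaling moved the median gene by 0.14 at 6 days and 0.15 at 10 days, and upper-quartile scaling by 0.19 and 0.08.

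Lists with fewer than 3 tested genes were given as single values. Otx2 was the forebrain and midbrain gene tested, and is also in the primed epiblast list. Its level was 5.89 FPKM in the control, 0.447 at 0 days, 6.09 at 6 days and 4.47 FPKM at 10 days. Ddc, of transmitter synthesis, was at 7.30, 4.48, 7.98 and 10.4 FPKM, and Cdkn1a, the cell cycle inhibitor p21, at 64.9, 122, 182 and 233 FPKM. Csf1r, a macrophage receptor that trophoblast also carries, was at 0.0281, 0.803, 1.44 and 4.15 FPKM, and Cd68 at 1455, 572, 920 and 736 FPKM. Cd68 (chromosome 11, 69664213 to 69666153) lies next to the translation factor gene Eif4a1 on the same strand, so its level is uncertain. None of the 3 receptor and channel genes in the table reached 1 FPKM, and the mitochondrially encoded genes were not analysed here.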

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

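The alternatives that keep the highest row of a repeated symbol and that leave out small and ribosomal RNAs were chosen after seeing the data; the others were chosen before the data were examined. Of 14 counts under these alternatives, 103 values stayed within 1.5 times the main count and 19 did not. The 14 values with no filter on low values could not change, since a gene below 1 FPKM in every library cannot reach 2-fold once 1 is added. At 4-fold or more, by its own construction, fewer genes were counted: 192 higher and 153 lower at 0 days against the control, 133 and 47 from 0 to 6 days, 29 and 7 from 6 to 10 days, 315 and 146 at 6 days against the control, and 469 and 189 at 10 days. A pseudocount of 0.1 adds genes with low values: 1111 were higher at 0 days against the control, 473 lower from 0 to 6 days, and 363 higher and 185 lower from 6 to 10 days; a pseudocount of 0.5 gave 98 lower in that last step. Upper-quartile scaling gave 497 lower genes at 0 days against the control and 76 lower from 6 to 10 days. Both follow from the rescaling, which moved the median gene by 0.18 in the first of these comparisons and by -0.11 in the last. With a filter at 5 FPKM fewer genes are tested, and 348 were highest at 0 days and 124 at 6 days. Of 980 list medians under the alternatives, 910 stayed within 1.5-fold of the main value and 70 did not; no list median at or outside percentiles 2.5 and 97.5 changed sign. Of 3967 differences of named genes, 3623 stayed within 1.5-fold, 344 moved further, all under the 2 other pseudocounts, and none that was 2-fold or more changed sign. Filters on low values, or leaving out small RNAs, cannot change the difference of a single gene, so the values under these alternatives were bound to stay. With a pseudocount of 0.1, 219 differences moved and 287 did not. With a pseudocount of 0.5, 125 moved and 381 did not. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Genes below about 0.122 FPKM on 1 kb rest on fewer than 3 fragments.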

Other observations

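The gene groups and tests in this part were chosen after the values were seen.

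Of 36 placental prolactins, placental cathepsins and Tpbp genes in the table, none reached 1 FPKM in the control or at 0 days, 9 did at 6 days and 16 at 10 days. The others stayed below 1 FPKM in every library. The highest of the 36 was at 0.150 FPKM in the control, 0.109 at 0 days, 19.3 at 6 days and 43.1 FPKM at 10 days. Prl2a1 was at 0.111 FPKM in the control and 24.8 FPKM at 10 days. Prl2c5 was listed at 0 and reached 22.6 FPKM, but the Prl2c genes are near-identical copies, so its value is uncertain. Of 23 secreted serum proteins of the liver and yolk sac, 2 reached 1 FPKM in the control, 7 at 0 days, 13 at 6 days and 17 at 10 days. Of those 17, 5 were already 2-fold or more higher than the control at 0 days, and 9 were higher and 1 lower at 6 than at 0 days. Spp2 was listed at 0 in the control and at 63.8 FPKM at 10 days, Kng1 at 0.0437 and 64.9 FPKM, and Apom at 2.47 and 69.4 FPKM. A gene low in the control enters such counts by rising, so its direction is no separate finding.

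MHC class I and antigen processing genes were higher at 0 days in 14 of 17 cases (median 2.13), lower again at 6 days in 8 (median -0.89) and higher at 10 days in 7 (median 0.80). H2-K1 was at 10.5, 68.9, 62.2 and 187 FPKM in the control and at 0, 6 and 10 days, and Psmb8, an immunoproteasome subunit, at 0.0337, 10.6, 1.87 and 3.87 FPKM; class I genes are near-identical, so single values are uncertain. Feedback targets of FGF and ERK signalling were lower at 0 days in 5 of 7 cases, with Etv5 at 114 and 8.89 FPKM, Spry2 at 120 and 29.4 FPKM, and Dusp6 at 85.5 and 35.5 FPKM. From 0 to 6 days 3 of 7 were higher and 1 lower (median 0.73), with Etv4 at 0.949 and 7.61 FPKM, and 6 of 7 were lower than the control at 10 days (median -2.22). Cytosolic ribosomal protein genes had medians of -0.31, 0.08 and 0.46 in the 3 successive steps, and of 34, none was 2-fold higher in any of them, while 1 was lower at 0 days than in the control and 1 lower at 6 than at 0 days.

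Some genes that were high in the control and low at 0 days were higher again at 6 days. Of 88 genes at 20 FPKM or more in the control and 4-fold or more lower at 0 days, 33 were 2-fold or more higher at 6 than at 0 days and 3 lower. The 0-day library both selects these genes and is the base of the rise, so selection alone favours rises over falls, and how far it does so cannot be measured with 1 library per group. The 2 other scalings did not remove the rises: they shifted the median gene between these libraries by at most 0.012, and the smallest rise among the 33 was 0.99 over 3 scalings. That smallest rise is set by the selection at 2-fold. In this step the 5 reference genes also had higher values, with a median of 0.33 (percentile 63.0). Scaling to the reference genes was not tried, so these values do not exclude scaling as part of the rises. Control-like cells would bring every abundant control gene at one share of its control level. Of all 1899 genes at 20 FPKM or more in the control, whatever their change, the 10 lowest stood at 6.07% of it or less at 6 days, Esrrb at 5.27% among them. The 33 genes gained a median of 22.3% of their control level, from 2.70% to 109%. For 26 of them the gain was over 1.5 times that bound, more than such cells alone would bring to those genes. The count is partly set by the selection, since a 2-fold rise needs a gain of at least the 0-day level plus 1 FPKM. For Ppa1, at 164 FPKM in the control and 37.3 FPKM at 0 days, that least gain was already above 1.5 times the bound. The split of 26 and 7 is therefore no separate argument against such cells. The other 7 stay open, and for these such cells and regained expression cannot be told apart. Among the 7, Sept1 (4.26% of its control level at 6 days) and Spry4 (6.07%) are themselves among the genes that set the bound. Krt42 (6.84%) and Etv4 (8.17%) stood in total under 1.5 times the bound. These genes could not have passed it whatever their gain. The rank and the factor were set after these values were seen, and over 12 choices of both between 10 and 33 genes lay above the bound. A different cell state that uses part of the control's genes, or a transient loss at 0 days, may be behind it, and neither was tested.

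From 6 to 10 days the 25 genes of 3 neural lists had a median of -0.72; 8 were 2-fold or more lower, 1 was higher, and the rest did not reach 2-fold. Median-ratio and upper-quartile scaling did not remove this: the largest shift of the median gene was 0.11, and the neural median was -0.73 and -0.80. The 5 reference genes also had lower values in this step, with a median of -0.40 (percentile 1.16). The 34 cytosolic ribosomal protein genes went the other way, with a median of 0.46. Scaling to either set was not tried, so these values do not exclude scaling as part of the neural fall. A change in cell makeup, with neural cells a smaller part of the culture at 10 days, could account for it, as could lower expression within neural cells: the 12 neural genes at 5 FPKM or more at 6 days had a median ratio of 0.592, with a range of 0.374 to 2.14, and both explanations give a ratio under 1. They cannot be told apart from bulk RNA of 1 library per stage.

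The extreme rows of Filip1l and Ispd both dropped at 10 days, as did the ribosomal RNA precursor Rn45s. For Filip1l, reads of ribosomal RNA counted on this gene are a candidate source: its ratio to Rn45s varied 1.98-fold over the 4 libraries while its own level varied 8.80-fold, and 4 of the tested symbols, Filip1l included, kept so even a ratio. The comparison rests on 4 libraries, and Filip1l also overlaps Cmss1. For Ispd the ratio was 10.1 in the control, 9.03 at 0 days and 4.53 at 6 days, within the 3-fold bound also used for Filip1l, but 0.00252 at 10 days. This 3990-fold range rests on the 10-day library, where the fall lies, and argues against the same source for that fall; the levels in the other 3 libraries were not tested. No biological explanation was tested for either. Of 34 symbols at 500 FPKM or more in 1 library and 50-fold lower in another, 31 were small or ribosomal RNAs and 29 were listed at 0 in at least 1 library.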
